A study of Mus musculus with 6 samples.

How the data were processed

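Gene expression was measured on Affymetrix arrays in cultured stromal cells from the bone marrow of adult mice, with 3 arrays of mesenchymal stem cells (MSC) and 3 arrays of neural crest stem cells (NCSC). Per the labels, the mice were female, 10 weeks old, of mixed C57BL/6 and SV129 background, and carried a Cre recombinase driven by Wnt1 sequences together with a lacZ reporter that Cre switches on. In such animals cells that descend from the neural crest, the embryonic tissue at the border of the neural plate, keep the reporter active. Per the labels' protocols, cells were grown in Mesencult medium for at least 5 passages and then selected as clones, total RNA was taken with an RNeasy kit, and biotin-labelled target was made with the 3' IVT Express kit. The labels call the samples biological replicates but do not say whether the replicates of a cell type came from separate animals or clones. The p-values therefore measure only the spread between these samples, which may be technical in part. If each cell type was grown from a single clone, a difference between clones cannot be told apart from one between cell types.

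The values deposited by the authors were probe set intensities on a linear scale, made with GCRMA (version not stated), a method that corrects for probe-specific background, normalizes between arrays and sums the probes of a set, per the submitters' processing notes. The scale was read from the values, which ran from 4.36 to 116597, with 33.5% to 34.5% of the probe sets of each array at that lowest value. The plan foresaw values already on a log2 scale, so each intensity was taken to log2 first and the rest of the plan was kept. The lowest value is 2.12 on the log2 scale. No further normalization was applied. All 6 columns of the table matched a sample by name.

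Of the 45101 probe sets, 34945 were annotated to 1 gene, 932 to several, 9160 were unnamed in the table used here and 64 were Affymetrix controls. The probe sets with 1 gene covered 18194 genes, and 34741 of them matched a RefSeq gene of the mouse assembly GRCm38.p6, which gave the chromosome. No coordinates are given because the table of values names no genome build. A probe set counted as above background when its log2 value was above 4, and it was kept when at least 3 of the 6 arrays were above that limit. Each gene was represented by the kept probe set with the highest mean over all arrays, which left 10501 genes for testing, and 4926 of these had more than 1 kept probe set.

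Differences between NCSC and MSC were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without trend, no covariate), and p-values were adjusted over the genes tested by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05, and calls with a difference of at least 2-fold were counted separately. Differences are NCSC minus MSC on the log2 scale, with the standard error (SE) of the fit. A gene was counted as similar when the 95% confidence interval of its difference lay between -1 and 1. Where the mean of the dimmer group was at or under the limit of 4, the fold is a lower bound, computed from the mean of the brighter group against the dimmer arrays with values under 4 set to 4, and written "at least N-fold". Such bounds need no value below the limit, whereas fitted differences of these genes rest on the floor of the deposited values.

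Gene lists were tested with limma's camera (preset correlation between genes of 0.01), which compares the genes of a list with all other tested genes, and adjusted over the 26 lists with at least 5 tested genes. The 32 lists covered neural crest, mesenchymal surface markers, osteoblast, adipocyte, chondrocyte, neuron, glia, melanocyte, macrophage and blood cell, endothelium, smooth muscle, epithelium, cell cycle and its inhibitors, extracellular matrix, matrix proteases, interferon, antigen presentation, Hox, signalling pathways, pluripotency, niche factors, growth factors, cytokines, stress, hypoxia, cholesterol, adhesion, axon guidance and sex-linked genes. The lists, the test designs, the alternatives and the rule for named genes were fixed before the data were examined. The camera test with a correlation estimated for each list, and limma's rotation test fry, were run as alternatives. Fry's calls rest on whether the genes of a list shifted in the same direction, not on whether they changed more than other genes. They answer another question than camera's, so ranges for lists are over the alternatives tested with camera. Chromosomes were tested in the same way as lists, over 20 chromosomes. Arrays were compared by Pearson correlation across the tested genes and by an exact permutation test over the 10 splits of 6 arrays into 3 and 3, which cannot give a p below 0.1.

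The genes named by the rule are the 12 with the largest and the 12 with the smallest difference among separated, called and at least 2-fold changed genes, passing over predicted genes, up to 4 members of each list with the smallest p, and 13 fixed genes. The 6 highest and 6 lowest differences among genes above the limit on all 6 arrays, and 42 further list members, were chosen after their values were seen. Of the genes on the lists, 55 had no probe set annotated to that gene alone, Ly6a among them, and they were not analysed here. Where a named gene had more than 1 kept probe set, the others were compared with the chosen one, and the 94 tested genes with 2 probe sets called in opposite directions include none of the genes named here. The fit was tested on simulated data for this comparison (10501 genes, 100 changed by 0.5 and 100 by 1 on the log2 scale). It recovered 23% of the smaller and 62% of the larger changes with 7 false calls, and made 0 calls on data without change. Far fewer genes were changed there than were called in the data, and noise was drawn for each gene alone. These rates therefore do not carry over to the data, where many genes of an array can depart together. The number of arrays, 3 per group, limits the precision.

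Alternatives changed one choice at a time: no filter or a stricter one (log2 above 6), a floor at 4, quantile normalization or median centring, the mean of a gene's probe sets, all probe sets as the unit, probe sets with names ending in _x_at or _s_at left out, a trended and robust fit, array weights, the replicate number as a block, a test against 2-fold, and each array left out in turn. Fits without an array kept the genes and probe sets of the fit to all 6 arrays. A fit without MSC 2 and NCSC 3 together, and one with every gene centred on the median log2 level of its chromosome in each array, were added after seeing the data. Control probe sets, unnamed probe sets and those with several genes entered no comparison between genes.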

Results

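Gene expression was profiled in 2 kinds of stromal stem cell grown from adult mouse bone marrow, MSC and NCSC, with 3 arrays of each. MSC are plastic-adherent cells able to form bone, fat and cartilage, and NCSC are stem cells descended from the neural crest. The series asks how alike and how different the 2 cell types are. Each array measured 45101 probe sets by GCRMA intensity, of which 45.2% to 45.5% lay above the limit of 4 on the log2 scale. The median log2 value of the 10501 tested genes was between 9.74 and 9.82 on every array.

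Arrays of different cell types differed far more than replicates did. The mean Pearson correlation across the tested genes was 0.991 between arrays of one cell type and 0.762 between arrays of different types, a difference of 0.228 (exact permutation test, one-sided p = 0.1, the smallest that 10 splits allow). With Spearman correlation the difference was 0.155, and without the filter on low values it was 0.0568. The first principal component held 94.9% of the variance. The median SD between replicates was 0.119 in MSC and 0.152 in NCSC, a ratio of 1.28. This ratio turned on single arrays, being 2.74 without MSC 2 and 0.606 without NCSC 3. MSC 1 and MSC 3 correlated at 0.997, with 0.409% of genes more than 2-fold apart, whereas MSC 2 had 2.69% and 2.62% of genes more than 2-fold from MSC 1 and MSC 3. Likewise NCSC 1 and NCSC 2 had 0.438% of genes more than 2-fold apart, and NCSC 3 had 4.98% and 4.63% of genes that far from NCSC 1 and NCSC 2.

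Of the 10501 genes, 6731 (64.1%) differed between NCSC and MSC in limma's test, 3672 higher and 3059 lower in NCSC. A difference of at least 2-fold was found for 3047 genes (29%), 1582 higher and 1465 lower in NCSC. Against a threshold of 2-fold in the test itself, 921 genes were higher and 837 lower. All 3 arrays of both cell types were above the limit for 9619 genes, while 329 genes were above it in all NCSC arrays and in no MSC array, and 325 the other way round. A value above the limit need not mean expression. L1cam in MSC and Krt5 in both cell types had constant values above it, which may be floors of their probe sets. Among the called genes named here with several kept probe sets, Cd44, Col1a1, Egfl7, Gpnmb, Idi1, Mcm4, Mcm5 and Uty had another one that differed in the same direction and was not called. For Id4, a bound from its brightest probe set is given, and another one, above the limit in both means, differed by 1.45. Without the filter on low values Gpnmb, Krt7, Cdc20, Mcm5, Mcm4, Cdc6, Eif2s3y, Snai2, Msx1, Egr2, Fcer1g, Des and Idi1 were not called, at adjusted p from 0.0521 to 0.138. The median difference of all tested genes was 0.0563 on the log2 scale.

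The largest rises in NCSC were mostly seen for genes that MSC did not express above the limit. Moxd1, a monooxygenase-like protein, was at least 1160-fold higher in NCSC, with a mean log2 intensity of 14.18 ± 0.15 (SD, n = 3) against 2.20 ± 0.0047. The transcription factor Sox2, known from neural and pluripotent stem cells, was at least 741-fold higher, at 13.53 ± 0.052 in NCSC and at the floor of 2.12 on all MSC arrays. The glial cadherin Cdh19 was at least 531-fold higher, the membrane protein Tenm3 553-fold, the adhesion molecule Cadm1 522-fold, the neuregulin receptor Erbb3 474-fold, Sntb1 449-fold, Klhl30 443-fold and Slc35f1 338-fold, each of these a lower bound. The adhesion molecule Cadm4 and the IGF-binding protein Igfbp3, for which 1 MSC array was above the limit, were at least 1500-fold and 684-fold higher. Igfbp5 also belongs to this group by its brightest probe set, which was at least 830-fold higher in NCSC, but its other kept probe set differed by -0.17 and was not called. Among genes above the limit on all 6 arrays, the largest rises were those of the cardiac troponin gene Tnnt2 (8.50 ± 0.25, SE), L1cam (8.12 ± 0.079), the phagocytic receptor Megf10 (7.50 ± 0.29), Uchl1 (7.20 ± 0.21), the immune adaptor Fyb (7.11 ± 0.28) and the protease Ctsc (6.74 ± 0.50). L1cam had the same value of 5.42 on all MSC arrays. That value may be a floor of its probe set, and its difference then a lower bound.

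The largest fall in NCSC was that of Efemp1. This matrix protein was at least 2340-fold lower in NCSC, at 2.16 ± 0.0068 against 15.19 ± 0.019 (SD, n = 3), and the matrix proteins Fbln2, Mgp and Vcan were at least 1490-fold, 1560-fold and 826-fold lower. Lower bounds of the fall were 1540-fold for the membrane protein Myadm, 1160-fold for the growth factor Fgf7, 1030-fold for the follistatin-like protein Fstl1, 878-fold for the myosin light chain Myl9, 877-fold for the imprinted adaptor Grb10, 592-fold for the metabolic kinase Pdk4, 515-fold for Ptx3 and 480-fold for the Wnt agonist Rspo2. Among genes above the limit on all arrays the largest falls were those of the cytokine receptor Osmr (-7.82 ± 0.30), smooth muscle actin Actg2 (-7.62 ± 0.91), podoplanin Pdpn (-7.50 ± 0.16), non-muscle myosin Myh10 (-7.03 ± 0.39), Ndn (-6.90 ± 0.51) and the proteoglycan Bgn (-6.68 ± 0.28).

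Tested genes of the neural crest were mostly higher in NCSC. Of 22 members with a probe set 13 were tested, of which 9 rose and 4 fell (13 adjusted over the list alone). Their median difference was 4.24. Without the filter, which 9 members did not pass, the list median was 0.41. The crest regulators Sox10 and Foxd3 had mean log2 intensities of 12.84 ± 0.23 and 9.02 ± 0.27 (SD, n = 3) in NCSC, against 4.30 ± 0.46 and 2.39 ± 0.43 in MSC, so that Sox10 differed by 8.54 ± 0.25 (SE) and Foxd3 was at least 32.5-fold higher. The p75 neurotrophin receptor Ngfr, used to sort crest stem cells, was at least 257-fold higher, and the receptor Ret at least 142-fold. Tfap2a, Pax3, Nes and Ets1 rose by 4.24, 4.75, 3.77 and 1.32. Members that were lower in NCSC were Sox9, at least 7.16-fold, Twist1 (-1.92 ± 0.25), Snai2 (-0.99 ± 0.26) and Msx1 (-0.73 ± 0.24), of which Snai2 and Msx1 lost their call without MSC 1 (adjusted p = 0.0542 and 0.0934, within ranges of 0.00141 to 0.0748 and 0.00326 to 0.123 over all settings). Msx1 was also not called without MSC 2 (0.0535) or MSC 3 (0.1), and was -0.47 without NCSC 1. Wnt1 was at the floor of 2.12 on all arrays. The list was called upward (camera adjusted p = 0.0333, and adjusted p = 0.288 with an estimated correlation), and not called without NCSC 3 (0.0743, range over the alternatives tested with camera 0.0143 to 0.288).

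**Figure D1:**
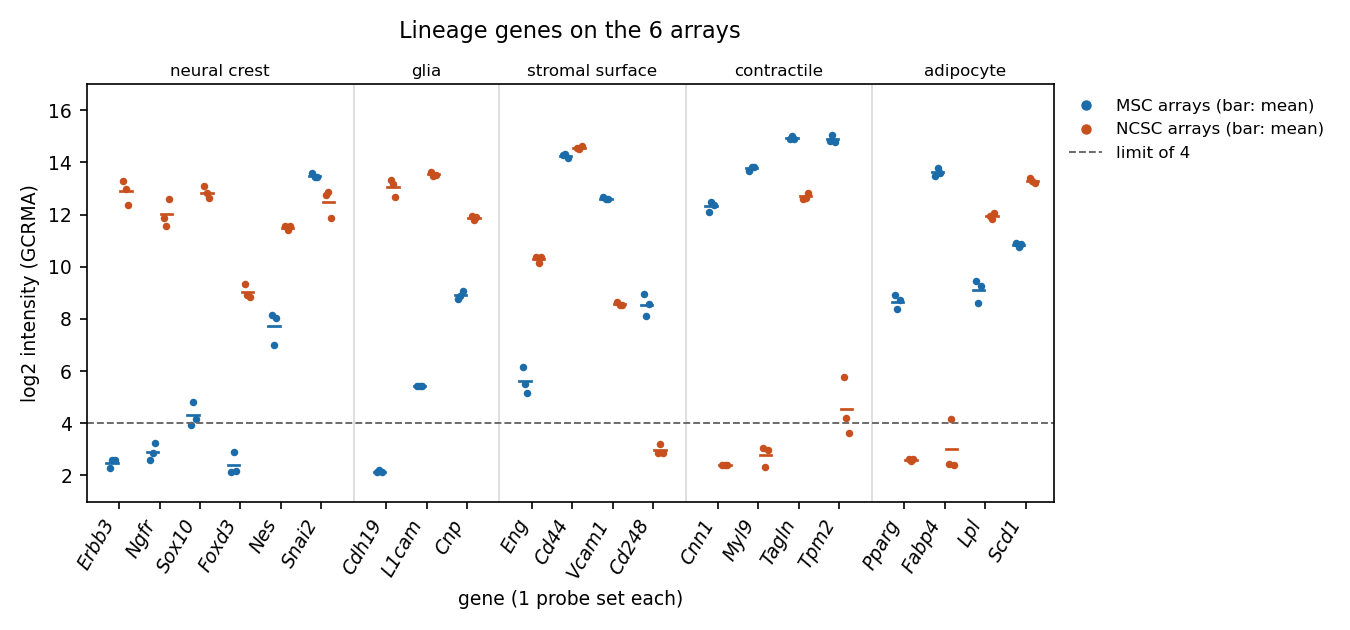
Log2 GCRMA intensity (vertical axis) of lineage genes (horizontal axis, grouped by list) on each MSC and NCSC array, with a bar for the mean of each cell type and a dashed line at the limit of 4. Erbb3, Ngfr, Foxd3 and Cdh19 lie under the limit on all MSC arrays and above 9 in the NCSC mean, Cnn1, Myl9 and Pparg lie under it on all NCSC arrays, and Cd44 differs by 0.31.

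Genes of Schwann cells and other glia also rose. Of 17 members with a probe set 10 were tested and all of these were called, 9 of them higher in NCSC (10 adjusted over the list alone). Their median difference was 3.53, or 2.59 with genes under the limit at their bound. Without the filter, which 7 members did not pass, the list median was 1.83. The adhesion molecule L1cam rose by 8.12 ± 0.079 (SE), from 5.42 on all MSC arrays, a value that may be a floor. The myelin enzyme Cnp rose by 2.97 ± 0.11. The lipid-binding protein Fabp7, typical of immature glia, was at least 17.8-fold higher, or 43.9-fold without NCSC 3 and 11.1-fold without NCSC 2. The member that was lower, Egr2 (-0.35 ± 0.11), a regulator of myelination, was not called without MSC 1, MSC 3, NCSC 1 or NCSC 2 (adjusted p = 0.0966, 0.0919, 0.0598 and 0.0855, range 0.002 to 0.344), and was 0.11 with chromosome medians removed. As a list these genes were called upward (adjusted p = 0.00149, and adjusted p = 0.288 with an estimated correlation). Of 22 neuronal genes 6 were tested, 4 higher and 1 lower in NCSC (5 adjusted over the list alone), and the list was not called (adjusted p = 0.291). The ubiquitin hydrolase Uchl1 rose by 7.20 ± 0.21, Map2 by 1.97 ± 0.18 and Tubb3 by 0.97 ± 0.22, while Stmn2 was at least 4.72-fold lower, or 9.3-fold without MSC 2. The 3 tested melanocyte genes were all higher (3 adjusted over the list alone), Mitf, the master regulator of the pigment lineage, by 2.07 ± 0.18, Rab38 by 6.50 ± 0.61 and Gpnmb by 0.87 ± 0.26. Gpnmb was not called without MSC 1, MSC 3, NCSC 1 or NCSC 2 (0.0903, 0.0902, 0.0908 and 0.0879, range 0.000249 to 0.11). On the pluripotency list 4 of 17 genes were tested and 4 called (4 adjusted over the list alone), with Sox2 and Tbx3 (1.37 ± 0.092) higher and Klf4 (-2.98 ± 0.17) and Klf2 (-2.17 ± 0.20) lower. Its median (-0.40) and mean (1.91) differ in sign.

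Surface markers of mesenchymal stromal cells did not move together. Of 15 tested members 8 were higher and 6 lower in NCSC (14 adjusted over the list alone), with Itgav not called (0.15 ± 0.077), and the list was not called (adjusted p = 0.729). The endothelial and stromal antigen endoglin (Eng) rose by 4.69 ± 0.25 (SE), the ectonucleotidase Nt5e was at least 22.8-fold higher, the membrane glycoprotein Cd200 at least 84.1-fold higher, and the NG2 proteoglycan Cspg4 rose by 2.31 ± 0.12. Vcam1 and the PDGF receptor Pdgfra fell by 4.04 ± 0.078 and 3.17 ± 0.28 on the log2 scale, and the pericyte marker Cd248 was at least 23.3-fold lower. The hyaluronan receptor Cd44 had means of 14.25 ± 0.089 in MSC and 14.56 ± 0.055 in NCSC, a difference of 0.31 ± 0.084 with a 95% confidence interval of 0.11 to 0.52. It was not called without MSC 1, MSC 3 or NCSC 1 (0.0503, 0.0679 and 0.0525, range 0.00375 to 0.448) and was -0.10 with chromosome medians removed. Itgav was called higher with a trended and robust fit (0.0452), array weights (0.0173) or without MSC 2 and NCSC 3 together (0.0435), and lower with chromosome medians removed (-0.26, adjusted p = 0.0421), within a range of 0.0173 to 0.345. Thy1 was at the floor of 2.12 on all arrays. The list's camera test pointed up, and fry's down.

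Genes of the mesenchymal lineages differed by gene. Of 21 osteoblast genes 4 were tested and 4 were lower (4 adjusted over the list alone), among them osteoglycin (Ogn), at least 138-fold, the phosphate regulator Phex, at least 6.48-fold, Smpd3, at least 5.94-fold, and the collagen chain Col1a1, by 0.64 ± 0.13 (SE) on the log2 scale. With the mean of its probe sets Col1a1 was not called (0.0551). Of 12 adipocyte genes 4 were higher, 3 lower and 5 not called (7 adjusted over the list alone). Pparg, the master regulator of fat cells, was at least 25.4-fold lower in NCSC and the lipid carrier Fabp4 at least 752-fold, whereas the lipase Lpl and the desaturase Scd1 rose by 2.84 ± 0.22 and 2.45 ± 0.092. The adipocyte list was not called (adjusted p = 0.945), with a median of 0.29 and a mean of -0.80. Of 6 chondrocyte genes 4 were higher and 1 lower (5 adjusted over the list alone), and the list was not called (adjusted p = 0.208). Sox6 was at least 207-fold higher, Matn2 and Matn3 rose by 1.54 ± 0.11 and 1.29 ± 0.24, and Sox9 was lower. Sox5 was at least 1.6-fold higher, but was not called with a floor at 4 (0.0515, range 0.000254 to 0.0515).

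Contractile genes fell together. Of 15 tested smooth muscle and myofibroblast genes 13 were lower in NCSC and 1 higher (14 adjusted over the list alone), with a median difference of -1.49. Calponin Cnn1 and Myl9 were at least 318-fold and 878-fold lower, tropomyosin Tpm2 was lower by 10.34 ± 0.52 (SE) and Tagln by 2.22 ± 0.092 on the log2 scale, and smooth muscle actin Acta2, bright in both cell types, differed by -1.49 ± 0.16, while its other probe set had means of 8.31 in MSC and 2.67, under the limit, in NCSC. Desmin (Des) was at least 1.94-fold higher in NCSC, a call lost without the filter (0.0625, range 0.00078 to 0.0625), and Tpm1 was not called (0.082 ± 0.091). Camera called this list downward (adjusted p = 0.000673, and adjusted p = 0.331 with an estimated correlation). Of 30 extracellular matrix genes 10 were higher and 13 lower (24 called adjusted over the list alone), and the list was not called (adjusted p = 0.144, median -0.092, mean -1.95). The matrix glycoprotein Tnc was at least 485-fold lower, while periostin (Postn) and the basement membrane collagen Col18a1 rose by 2.62 ± 0.23 and 6.45 ± 0.37. Of 19 matrix proteases and inhibitors 8 were higher and 8 lower (16 adjusted over the list alone), with a median of 0.041, a mean of -0.20 and an adjusted p of 0.835, and the median ran from -0.045 without NCSC 1 to 0.22 without NCSC 3. Mmp16, Mmp23 and Ctsk were at least 9.05-fold, 35.2-fold and 11.3-fold lower, and the inhibitor Timp3 fell by 0.92 ± 0.073. Of 16 epithelial genes 3 were tested and 2 were lower (2 adjusted over the list alone). The keratin Krt19 was at least 258-fold lower. Krt7 (-1.32 ± 0.38) was not called without MSC 1 or MSC 3 (0.0704 and 0.0553, range 0.00461 to 0.0959), and Krt5 was at 5.05 on all arrays. That constant Krt5 value may be a floor of its probe set.

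The tested Hox genes, which record position along the body axis, were mostly lower in NCSC. Of 33 members with a probe set 17 were tested. Of these 12 were lower, 2 higher and 3 not called (14 adjusted over the list alone), with a median difference of -1.90. Without the filter, which 16 members did not pass, the list median was -0.046. Hoxa9 was at least 342-fold lower, with means of 12.42 ± 0.14 (SD, n = 3) in MSC and 3.13 ± 0.48 in NCSC. Hoxa10, Hoxc13, Hoxc10 and Hoxa5 were lower by 6.90 ± 0.29 (SE), 5.37 ± 0.33, 4.25 ± 0.23 and 1.98 ± 0.10 on the log2 scale. On NCSC 1 and NCSC 2 Hoxa10 was just under the limit (3.97 and 3.998) and Hoxc13 had the same value of 4.52. The differences of Hoxa10 and Hoxc13 may therefore rest in part on background. The 2 that rose were Hoxb2, at least 9.22-fold, and Hoxb4, by 3.23 ± 0.29, both from the anterior part of the Hoxb cluster. Hoxb3 (0.64 ± 0.30), Hoxc4 (0.19 ± 0.19) and Hoxb6 (-0.12 ± 0.13) were not called, although Hoxb3 and Hoxc4 were called higher without MSC 2 (0.00315 and 0.0446, ranges 0.00315 to 0.281 and 0.0256 to 0.779). The list was called downward (adjusted p = 0.0119, and adjusted p = 0.308 with an estimated correlation).

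**Figure D2:**
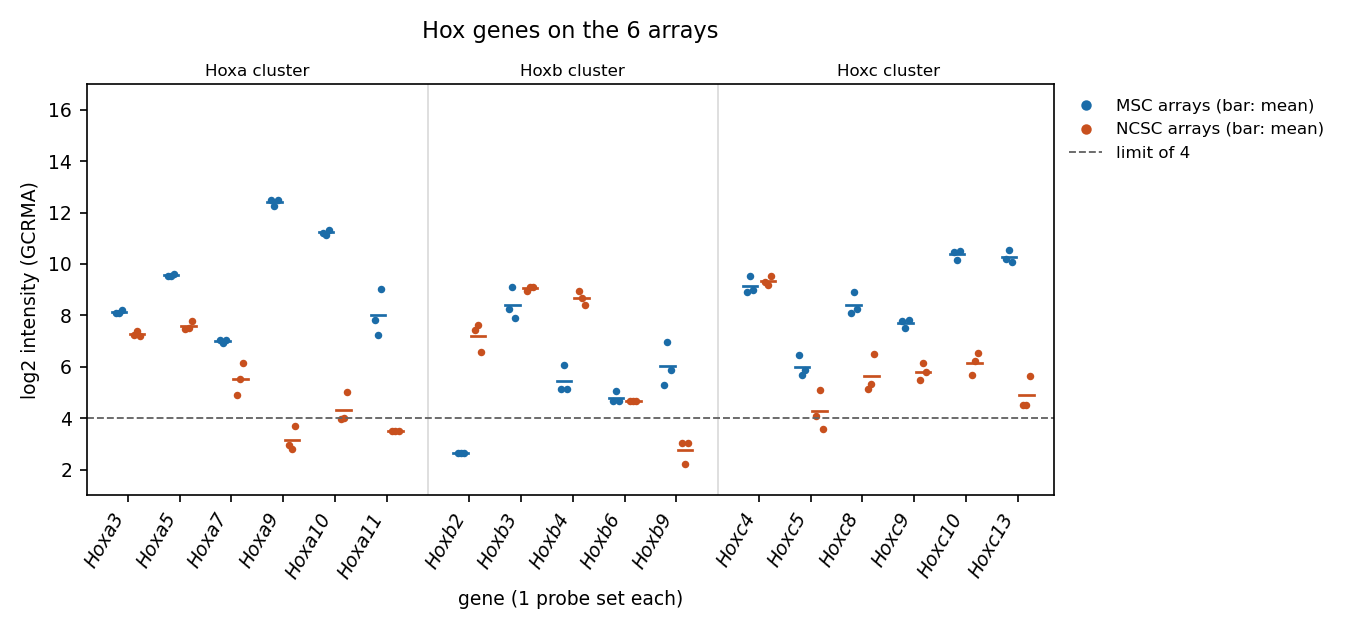
Log2 GCRMA intensity (vertical axis) of the 17 tested Hox genes (horizontal axis, ordered within clusters) on each MSC and NCSC array, with a bar for the mean of each cell type and a dashed line at the limit of 4. Hoxa9 falls from a mean of 12.42 in MSC to 3.13 in NCSC, and Hoxb2 and Hoxb4 are the members called higher in NCSC.

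Factors with which stroma keeps blood stem cells were mostly lower in NCSC. Of 14 tested members 10 were lower and 3 higher (13 adjusted over the list alone), with a median difference of -1.54. The growth factor Ptn was at least 324-fold lower (658-fold without MSC 2), Bmp4 at least 38.1-fold and Angpt1 at least 11.3-fold, and the stromal transcription factor Foxc1 was lower by 3.83 ± 0.095 (SE). The chemokine Cxcl12 differed by -0.58 ± 0.084 in its brightest probe set, a call lost with chromosome medians removed (-0.27, adjusted p = 0.0631, range 1.42e-05 to 0.0631). In its other kept probe set it differed by -2.64, also called. The cytokines Lif (2.64 ± 0.12) and Il6 (1.61 ± 0.25) and the Notch ligand Jag1 (2.83 ± 0.15) were higher, and Igf1 was not called (-0.0051 ± 0.14), although it was higher in NCSC with chromosome medians removed (0.45). The list was called downward (adjusted p = 0.0184, and adjusted p = 0.288 with an estimated correlation). It was not called without MSC 2 and NCSC 3 together (0.0555) or with chromosome medians removed (0.0692), within a range of 0.00642 to 0.288 over the alternatives tested with camera.

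Immediate early and stress genes fell more often than they rose. Of 23 tested members 14 were lower and 4 higher (19 called adjusted over the list alone), with a median difference of -1.16. The small heat shock protein Hspb1 was at least 440-fold lower in NCSC and the antioxidant enzyme Nqo1 at least 4.63-fold, and the immediate early genes Ier2 and Egr1 were lower by 3.47 ± 0.20 (SE) and 1.94 ± 0.15. Higher members were the heat shock gene Hspa1a (1.83 ± 0.23), Nr4a1 (1.26 ± 0.24), Jun (0.83 ± 0.18) and Ier3 (0.42 ± 0.11), the last not called without MSC 1, MSC 3, NCSC 1 or NCSC 2 (0.0604, 0.0608, 0.058 and 0.0515, range 0.000506 to 0.348). As a whole the list was called downward (adjusted p = 0.0122, and adjusted p = 0.288 with an estimated correlation).

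Some genes known from macrophages and blood cells were higher in NCSC, without the leukocyte antigen Ptprc (CD45), which was at the floor of 2.12 on all arrays. Of 21 members with a probe set 6 were tested, and 5 of them were higher (5 adjusted over the list alone). They were the lysosomal protein Cd68, at least 27.9-fold, the lysosomal protein Laptm5 (5.40 ± 0.68, SE), the lysozymes Lyz2 (1.97 ± 0.18) and Lyz1 (1.51 ± 0.15), and the receptor subunit Fcer1g (0.79 ± 0.22), which was not called without NCSC 1 (0.0682, range 0.00944 to 0.29). Csf1r was not called (adjusted p = 0.188), with means of 3.81 in MSC, under the limit, and 4.34 in NCSC. The list was called upward (adjusted p = 0.0333, and adjusted p = 0.288 with an estimated correlation), but not without NCSC 3 (0.0557) or without the filter on low values (0.728), within a range of 0.0199 to 0.728 with camera. Of 18 endothelial genes 2 were tested and both were called (2 adjusted over the list alone), the VEGF receptor Flt1 higher by 2.61 ± 0.25 and Egfl7 lower by 1.51 ± 0.19.

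Components of signalling pathways changed in both directions, and camera called none of the 3 lists. Fry called the Wnt list and the BMP and TGF-beta list downward (adjusted p = 7.5e-05 and 0.00651) and the Notch list upward (0.000138). Of 18 Wnt pathway genes 9 were higher and 7 lower in NCSC (16 adjusted over the list alone). The intracellular inhibitor Nkd2 and the secreted inhibitor Frzb were at least 214-fold and 143-fold higher and the transcription factor Lef1 rose by 3.94 ± 0.20 (SE), whereas the secreted Rspo2, Dkk3 and Sfrp2 were at least 480-fold, 143-fold and 21.6-fold lower. The Wnt list had a median of 0.20, a mean of -0.086 and an adjusted p of 0.998, and its camera test pointed up and fry's down. Of 29 BMP and TGF-beta genes 10 were higher and 14 lower (24 adjusted over the list alone, list adjusted p = 0.352). Id4 was at least 54.8-fold higher, Ltbp2 at least 19.1-fold lower, and the activin subunit Inhba lower by 5.57 ± 0.20. Of 12 Notch genes 7 were higher and 3 lower (10 adjusted over the list alone, list adjusted p = 0.6). The receptors Notch4 and Notch1 and the ligand Dll1 rose, at least 38.9-fold, by 2.60 ± 0.11, and at least 14.5-fold, while Notch3 was at least 48.5-fold lower.

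Cell cycle genes were measured against a replicate spread that was itself large. Of 29 tested members 4 were lower in NCSC, 25 were not called and 0 were called by limma adjusted over the list alone, against 9 at an unadjusted p under 0.05. The called genes were Cdc20 (-0.998 ± 0.233, SE) and the replication genes Mcm5 (-1.50 ± 0.37), Mcm4 (-0.84 ± 0.26) and Cdc6 (-1.51 ± 0.49). Cdc20 and Mcm5 were not called with chromosome medians removed (0.084 and 0.25, ranges 6.72e-05 to 0.084 and 4.85e-05 to 0.25). Mcm4 and Cdc6 lost their call without MSC 1, MSC 3, NCSC 1 or NCSC 2 (0.0825, 0.0936, 0.0935 and 0.0838 for Mcm4 and 0.107, 0.0984, 0.109 and 0.112 for Cdc6, ranges 0.000332 to 0.116 and 0.000144 to 0.138). The median of the list on NCSC 3 was 1.09 above that of the other 2 NCSC arrays, and on MSC 2 it was -0.34 against the other 2 MSC arrays. The list was not called (median -0.41, adjusted p = 0.107), but was called downward without NCSC 3 (median -0.81, adjusted p = 0.000195), with array weights (0.00127), with chromosome medians removed (0.0211) and with the replicate number as a block (0.0333), within a range of 4.48e-06 to 0.911 with camera, and its median was -0.25 without NCSC 1 and -0.26 without NCSC 2. Of 17 cell cycle inhibitors and p53 targets 2 were higher and 9 lower (11 adjusted over the list alone), with a median of -0.73 and an adjusted p of 0.064. Ccng1 fell by 2.10 ± 0.097, Perp was at least 16.5-fold lower, Ei24 was lower by 1.33 ± 0.13 and Gadd45a higher by 1.52 ± 0.12. This list was called downward without MSC 1, MSC 3 or NCSC 3 (0.0396, 0.0447 and 0.0488), without the filter (0.0449) and with the replicate number as a block (0.0456), within a range of 0.0396 to 0.634 with camera.

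Interferon-induced genes were mostly lower in NCSC, and 1 MSC array stood out on them. Of 17 tested members 4 were higher and 11 lower (15 adjusted over the list alone), with a median of -1.36, and the list was not called (adjusted p = 0.144). Usp18 was at least 45.5-fold lower and Rtp4 lower by 4.37 ± 0.37 (SE), while the chemokine Cxcl10 and the GTPase Gbp2 were higher by 4.77 ± 0.48 and 2.44 ± 0.26. On MSC 2 the median of the list was 1.39 above the other 2 MSC arrays, and without MSC 2 the list differed by a median of -0.79. Of 11 genes of MHC class I and antigen processing 2 were higher, 2 lower and 7 not called (4 adjusted over the list alone, list adjusted p = 0.835), with a median of -0.30, or -0.039 without MSC 2. The peptide transporter Tap1 was at least 14.9-fold lower, and Psmb10 differed by -0.60 ± 0.11, Tapbp by 0.83 ± 0.14 and B2m by 0.40 ± 0.095. With chromosome medians removed Psmb10 differed by 0.37 and B2m by -0.012.

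Growth factors, cytokines and adhesion molecules changed in both directions. Of 16 neurotrophic and growth factors 9 were higher and 5 lower (14 adjusted over the list alone, list adjusted p = 0.392, median 1.09, mean 0.165). The GDNF family ligand Artn and the PDGF chain Pdgfb were at least 73.7-fold and 253-fold higher in NCSC, Gdnf and Pdgfa rose by 4.81 ± 0.33 (SE) and 2.63 ± 0.074, and Bdnf fell by 3.37 ± 0.13. Of 16 cytokines and chemokines 5 were higher and 7 lower (12 adjusted over the list alone, list adjusted p = 0.608). Ccl2 rose by 2.26 ± 0.15, the prostaglandin enzyme Ptgs2 fell by 3.87 ± 0.21, and the acute phase protein Saa3 was at least 5.39-fold lower. Of 20 adhesion molecules 12 were higher and 7 lower (19 adjusted over the list alone, list adjusted p = 0.656), with integrin Itgb3 at least 49-fold higher, Cdh13 at least 100-fold lower and Cdh11 changed by -4.83 ± 0.32. Itga1 was not called (-0.15 ± 0.23), but was called higher with chromosome medians removed (0.70, adjusted p = 0.0379, range 0.0379 to 0.943). Of 29 axon guidance genes 12 were higher and 12 lower (25 called adjusted over the list alone, list adjusted p = 0.716). Sema3b and the receptor Plxnd1 rose by 6.28 ± 0.15 and 4.96 ± 0.13, Sema6a was at least 6.78-fold higher, and the receptor Robo1 was at least 41.5-fold lower.

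Metabolic lists were not called. Of 22 hypoxia and glycolysis genes 3 were higher, 5 lower and 14 not called (8 adjusted over the list alone, list adjusted p = 0.144). The list was called downward with array weights (0.0493) and without MSC 2 and NCSC 3 together (0.043), within a range of 0.043 to 0.878 with camera. The vasodilator peptide Adm was at least 190-fold lower in NCSC, the hexokinase Hk2 fell by 1.01 ± 0.19 (SE), the glucose transporter Slc2a1 by 0.76 ± 0.12 and Pfkp by 0.76 ± 0.095, although with chromosome medians removed Pfkp differed by 0.088 and Slc2a1 by -0.30, neither called (0.461 and 0.0795, ranges 2.71e-05 to 0.461 and 4.77e-05 to 0.0795). Of 17 cholesterol synthesis genes 6 were higher and 1 lower (7 adjusted over the list alone, list adjusted p = 0.208, median 0.39, or 0.16 without MSC 2), with Dhcr7 and Insig1 higher by 3.802 ± 0.344 and 1.70 ± 0.215 and Idi1 changed by -0.88 ± 0.22, or by -0.037 with chromosome medians removed. With an estimated correlation camera called 0 of the 26 lists, against 3 at an unadjusted p under 0.05. The rotation test fry called 19. It tests whether the genes of a list shifted in the same direction, not whether they changed more than the other genes. The 2 counts therefore answer different questions.

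Beside the differences, 5812 genes (55.3%) were similar, their 95% confidence interval lying within 2-fold, and 2433 of these also differed in limma's test by a small amount. Similar genes need not be expressed. Krt5, counted among them, had the same value of 5.05 on all arrays, which may be a floor of its probe set. Both called and similar were, among others, B2m (interval 0.17 to 0.63), Cd44 (0.11 to 0.52) and, by its brightest probe set, Cxcl12 (-0.79 to -0.38). Each of these had a mean above 14 in both cell types and lost its call with chromosome medians removed. The other kept probe set of Cxcl12 differed by -2.64. Col1a1 (-0.95 to -0.33), Psmb10 (-0.87 to -0.32) and Pfkp (-0.99 to -0.53) were also similar while called lower.

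The differences were unevenly spread over the chromosomes. Of 20 chromosomes 12 passed camera's test, 7 shifted up and 5 down in NCSC. With an estimated correlation chromosome 8 alone was called (adjusted p = 0.00194). On chromosome 8, 450 of 569 tested genes were lower in NCSC and 41 higher, with a median of -0.94 (adjusted p = 1.16e-22), and 89.5% of its genes lay below the median of all genes. Medians were -0.65 on chromosome 13, -0.43 on 4, -0.34 on 10 and -0.32 on 6, and 0.47 on chromosome 1, 0.47 on 5, 0.42 on 12, 0.34 on 3, 0.33 on 2, 0.31 on 7 and 0.29 on 16. The SD of the chromosome medians was 0.385 between the cell types and at most 0.0906 between arrays of one type. With the genes past the threshold left out chromosomes 5, 6 and 8 were called. Chromosome 9 was called downward without NCSC 3 (adjusted p = 0.0225, range 0.0225 to 0.89).

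**Figure D3:**
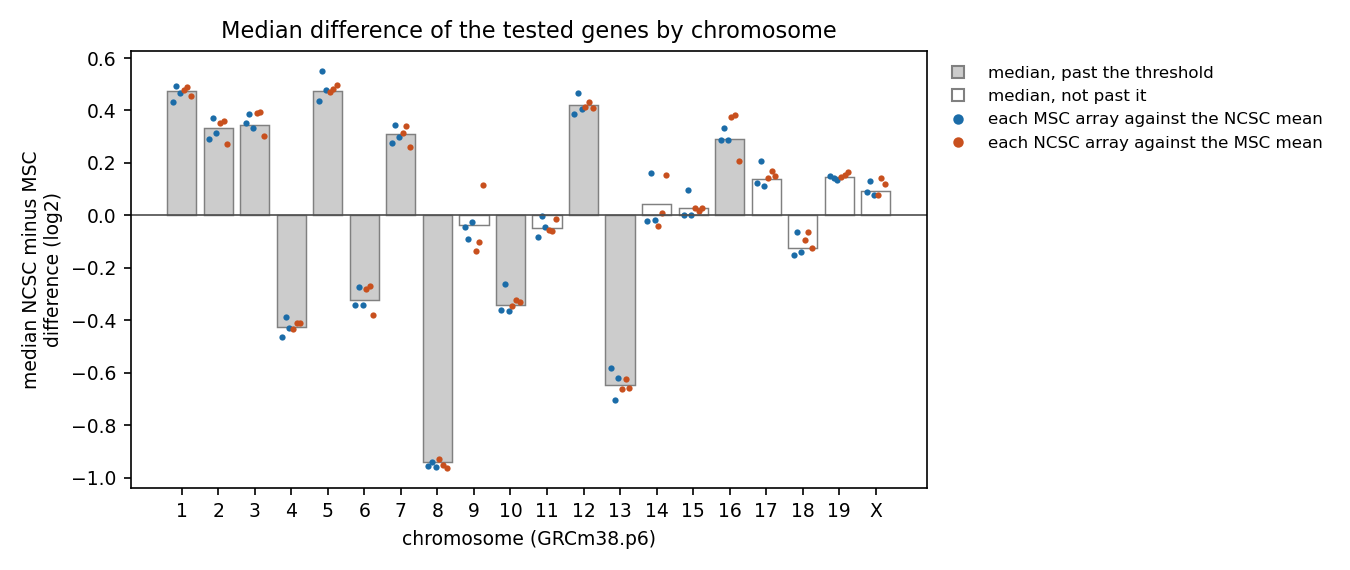
Median NCSC minus MSC difference (vertical axis, log2) of the tested genes of each chromosome (horizontal axis, assembly GRCm38.p6), as a bar that is grey where camera's test was passed. Points give each array against the mean of the other cell type with the same sign, and on chromosome 8 all 6 lie near the median of -0.94.

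Of 5 sex-linked genes 3 were tested and called (3 adjusted over the list alone), and their median (-0.50) and mean (1.79) differ in sign. The labels give the mice as female, but the Y-linked genes Eif2s3y and Uty had mean log2 intensities of 11.04 ± 0.22 and 8.64 ± 0.045 (SD, n = 3) in MSC and 10.54 ± 0.24 and 7.84 ± 0.25 in NCSC. The Y-linked Kdm5d was at 2.15 ± 0.019 in MSC and 8.83 ± 0.36 in NCSC, at least 28.4-fold higher. The Eif2s3y call (-0.50 ± 0.17, SE) was lost without MSC 2, MSC 3, NCSC 1 or NCSC 2 (adjusted p = 0.0963, 0.0741, 0.116 and 0.118, range 0.00227 to 0.12). Xist, the RNA of the inactive X chromosome, was at most 2.13 on any array in any of its 3 probe sets.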

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

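Signal was also present in probe sets that entered no comparison between genes. Of 1811 tested probe sets without a gene name in the table used here, 824 were called between NCSC and MSC, and 469 differed at least 2-fold, 234 higher and 235 lower in NCSC. Of 553 tested probe sets annotated to several genes, 290 were called and 108 differed at least 2-fold, 57 higher and 51 lower. These probe sets are given as counts, and no explanation was tested.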

How the results depend on the processing

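Each result was recomputed under its own alternatives, the chromosomes only with an estimated correlation, with called genes left out and without each array. Lists and named genes were not recomputed for all probe sets or the test against 2-fold, although the former was planned for named genes. Of the alternatives 2 were chosen after seeing the data, the fit without MSC 2 and NCSC 3 together and the one with chromosome medians removed. For the 189 named genes, 3301 values kept their side of the threshold (14 of them, uncalled, with another sign), 69 lost a call, 8 gained one and 10 changed direction; for the lists the values were 479 (15 with another sign), 14, 23 and 1, with 11 of the gains and the change of direction coming from fry, which has another null, and for the chromosomes 139 (4 with another sign), 20, 1 and 0. Without the filter 12828 genes were similar and the difference in array correlation was 0.05679, because undetected genes then entered both. That difference was 0.2893 with the stricter filter, 0.1899 with a floor at 4, 0.2511 with the mean of probe sets and 0.155 with Spearman correlation, and the cause was not tested. With all probe sets as the unit, more units were tested, and 12362 were called, 6711 higher and 5651 lower, 3104 and 2744 of them at least 2-fold. There were 11453 similar units. The correlation difference was then 0.1711, and the cause was not tested. Tested against 2-fold, 1758 genes passed, 921 higher and 837 lower, as a stricter null leaves fewer. Camera with an estimated correlation called 0 lists (3 at an unadjusted p under 0.05) and 1 chromosome. Fry, which tests for a shift in the same direction, called 19 lists. Without the genes past the threshold 3 chromosomes were called. Leaving out each array in turn gave 5706 to 7184 genes, 3152 to 3867 higher and 2554 to 3317 lower, 1499 to 1676 and 1399 to 1538 at least 2-fold, 5323 to 5803 similar, 7 to 8 lists and 12 to 13 chromosomes. The correlation difference then ran from 0.2256 to 0.2358, and the ratio of spreads from 0.6062 without NCSC 3 to 2.736 without MSC 2. Without MSC 2 and NCSC 3 together 7773 genes and 6 lists were called and Igf1 changed to 0.2103. Without probe sets ending in _x_at or _s_at, Igfbp5 was at -0.1688, as its other probe set then stands for it, and the macrophage list had too few genes for a test. The Wnt list, with a median of 0.2026, was called downward by fry, and the cause was not tested. With chromosome medians removed 6163 genes and 7 lists were called, and by that construction Psmb10 changed to 0.3749, B2m to -0.01225, Pfkp to 0.08806, Cd44 to -0.09988, Itgav to -0.2642, Egr2 to 0.1137, Igf1 to 0.4545 and Itga1 to 0.6977. This centring removed the median level of a chromosome on each array, not its median difference, and can remove more. Pfkp moved from -0.7577 to 0.08806, although its chromosome 13 had a median difference of -0.647. Such changes of direction may therefore depend on the centring. Deviations of arrays with the same replicate number correlated at -0.0985, 0.0621 and 0.0729, and those with different numbers at -0.106 to 0.11. With 3 arrays per group, MSC 2 and NCSC 3 dominate these deviations, so they cannot tell whether the numbers pair the samples. With the replicate block 6257 genes and 9 lists were called, cell cycle (camera adjusted p = 0.0333) and p53 targets (0.0456) added. Signal near background limits the folds of undetected genes, which are lower bounds.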

Other observations

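The tests of the sex-linked genes, of RNA degradation and of growth state were chosen after their results were seen, and the others were set before. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many called genes (6731, highest other 0). For called lists 4 of 10 splits gave as many (real 7, highest other 9), and for called chromosomes 8 of 10 (real 12, highest other 14). With 10 splits no share can go under 0.05. Every other split mixes the cell types on both sides, so part of their difference stays between the sides and part enters the spread within them. Camera compares genes with one another, so it can still call lists and chromosomes there. None of these counts, of genes, lists or chromosomes, can therefore tell whether the calls arose by chance.

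Whole chromosomes differed between the cell types, most of all chromosome 8, with a median of -0.94. At least 63.3% of the genes on each called chromosome lay on the side of its shift. A shifted median puts most genes on its side by construction, and uncalled chromosome 18 had 62.2%. This share therefore cannot decide on a few strongly changed genes for chromosome 16 (63.3%), whose median without called genes was 0.0078. On chromosome 8, 89.5% of the genes lay on the side of the shift, which argues against a few strongly changed genes there. Gene density is argued against too, with a Spearman rho of -0.0556 between chromosome medians and tested genes per length (Pearson -0.00533, permutation p = 0.814, 20 chromosomes). Of equal segments, in gene order, of the called chromosomes 100% had the sign of their chromosome. On the uncalled chromosomes 5 to 9 of the 10 segments had it. The segments cannot tell a shift of a whole chromosome from changed genes spread evenly along it. A difference in copy number between the cultured clones is a candidate explanation, a hypothesis that expression alone cannot settle. Other differences between the cell types stay open.

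The Y-linked Eif2s3y and Uty gave signal in both cell types and Kdm5d in NCSC alone, and Xist gave none, although the labels give the mice as female. The Y-linked Sry, Zfy2, Usp9y and Uba1y gave none either, at 2.12 to 2.15 on all arrays. For Kdm5d, cross-hybridisation with its X-linked relative Kdm5c is argued against, since Kdm5d was at most 2.16 on the MSC arrays, where Kdm5c was at 9.82. The mean of Kdm5d in NCSC was 8.83, so its 1 kept probe set argues against the female label for NCSC. MSC, without Kdm5d signal, are not covered by it. Uty and Eif2s3y were above the limit on all arrays, as were their relatives. Uty changed by -0.801 and its relative Kdm6a by 0.806, which argues against Kdm6a as the only source of the Uty signal. Cross-hybridisation as part of the Uty signal stays open. For Eif2s3y it stays open too, with a change of -0.499 against -0.15 for its relative Eif2s3x. Xist was at most 2.13 in any probe set on any array, a value that cells of male origin could give. The Y-linked genes without signal cannot decide the question, because no array of known male cells shows whether they would be detected.

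MSC 2 and NCSC 3 stood apart from the other arrays of their cell type. RNA degradation stays open for NCSC 3, whose 3' minus 5' difference of the actin control was 0.12 above the mean of the other 2 NCSC arrays (0.393 and 0.412), while on MSC 2 neither the actin nor the Gapdh difference was raised. The actin difference of NCSC 3 (0.522) was near those of MSC 1 (0.494) and MSC 3 (0.497), which did not stand apart. Its Gapdh difference was -0.0624, against -0.153 and -0.127 on NCSC 1 and NCSC 2. The median of the cell cycle list on NCSC 3 was 1.09 above the other 2 NCSC arrays, outside the range of random lists (-0.234 to 0.245), and on MSC 2 it was -0.339 (random -0.211 to 0.185), so a different growth state of those cultures is a candidate explanation. On MSC 2 the interferon-induced list was 1.39 above the other 2 arrays (random -0.405 to 0.302). The genes of the cell cycle and interferon-induced lists moved together (estimated correlation 0.946 and 0.856). Random lists hold unrelated genes, so a departure outside their range is weak evidence. A subclone with another chromosome content stays open, with a largest departure of 0.234, on chromosome 9 of NCSC 3.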
